A study of Mus musculus with 2 samples.

How the data were processed

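Chromatin from pooled retinae was immunoprecipitated with a custom antibody against Ronin for 1 sample, and libraries were made with the Ion Xpress Plus Fragment kit, per the labels' protocols. The other sample is titled as input, while its antibody label names normal rabbit IgG. Which of these it was is not given in the sources used here, and none of its own values were used. The peak list still depends on a control, since the authors' filter compared each candidate with one, per the file headers. The deposited peak list was called with HOMER 4.7 on build mm9, per the submitters' processing notes. The aligner is not given in the sources used here. Per the file headers, HOMER searched for peaks 191 bp wide at least 382 bp apart at a false discovery rate of 0.001, which set a threshold of 6 tags, and counted at most 1 tag per bp. Per the file headers, 47133 candidate peaks were found. Of these, 9531 were removed by the filter against the control, 241 by the filter against the surrounding 10000 bp and 1 for too few distinct positions. The first 2 filters each asked for a 4-fold excess and a Poisson p of 0.0001, per the file headers. These filters lower the number of close neighbours and of peaks in regions where the control was high. The score of each peak in the list deposited by the authors is 1 throughout, so it ranks nothing.

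Tags per peak were recovered from the order of the list, a step chosen after the list was seen. The list was taken to run by falling tag count and, within a count, by chromosome and position, so that each step back begins a lower count. The largest of the 43 groups was set to the threshold of 6 tags. The recovered tags sum to 266288, against 268208 in the header, and a shift by 1 tag would give 303648 or 228928. Counts at the top are lower bounds, since empty counts leave no step, and 74 peaks came out under 6 tags. On 20 simulated lists of 37360 peaks, counts up to 20 tags were recovered in 100% of peaks. Those lists were sorted in the assumed order and held no count under 6. They therefore do not test whether the deposited list is sorted that way. All peaks but 1 are 191 bp wide, and there were no duplicate intervals.

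The number of peaks, peaks per chromosome and spacing were planned before the data were examined. Peaks per chromosome were compared with span by a two-sided test with 100000 resamples and Benjamini-Hochberg adjustment at 0.05. Each resample drew the same number of peaks independently, in proportion to span. It is called a permutation test here, although no labels were permuted. In simulation the adjusted test found a chromosome of doubled density in 86% of lists of 400 peaks. The chi-square summed over all chromosomes called 7% of unchanged lists of 2000 peaks. How often the adjusted test per chromosome calls unchanged lists was not simulated. Spacing was compared with 1000 random placements within each chromosome's span, one-sided, without removing assembly gaps. A simpler version, with a distance of 50000 bp, fewer placements and made-up chromosomes of equal length, called 1% of simulated random lists of 500 peaks. It does not cover the distance of 5000 bp, the spans or the number of peaks used here. Chosen after the data were seen were the limit of 14 tags, the tag classes, gene density, the X chromosome ratio, windows of 1 Mb, positions within chromosomes, peaks near strong peaks and the candidate numbers. For positions within chromosomes, a split of chromosome 7 at a point picked by eye from the map was computed first. It was dropped for a Kolmogorov-Smirnov test on every chromosome, because a boundary picked from the data makes its own p too small.

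Gene positions of build mm9 were not used here. The planned share of peaks at promoters, motif searches, tests of 24 gene lists and scores at promoters were therefore not run. The rule for named genes took a fixed set of retinal genes and Ronin partners, the highest-scoring bound members of each list and the highest-scoring promoter peaks. It could not be applied, and no gene is named. Protein-coding genes per chromosome (21631 in all) were counted in a RefSeq gene table of assembly GRCm38, which is another build than that of the peaks. Only the chromosome of each gene was used, and none of its coordinates. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Exact intervals are at 95%. With 1 library, p-values describe peaks or chromosomes within it and not differences between retinae.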

Results

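Ronin (Thap11) is a DNA-binding protein with a THAP-type zinc finger. Its binding across the genome was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in the retina of wild-type mouse pups of the outbred CD-1 background at postnatal day 0. Each sample pooled more than 10 retinae. There was 1 Ronin ChIP sample and 1 control sample, with no replicates, and the question was where Ronin lies in the retinal genome. The values here come from the peak list of the Ronin ChIP sample, and the control was not analysed here as values of its own. The ChIP library held 3643141 tags (mapped reads), of which 268208 lay in peaks. That is 7.36% of the tags, with an exact Clopper-Pearson 95% interval of 7.34% to 7.39%. All intervals given here cover counting error only. Coordinates are in mouse build mm9, and positions relative to genes were not analysed here.

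The Ronin ChIP gave 37360 peaks on the 19 autosomes and the X chromosome, and most of them were low. Peaks of 6 or 7 tags made up 27676 of the list (74.1%), and the median peak had 7 tags. A small group stood above this mass: 395 peaks had 14 or more tags, which is 1.06% of the list (exact 95% interval 0.956% to 1.17%). These 395 are called strong peaks here. They were not screened for regions that give high signal whatever the antibody, so not all of them are shown to be Ronin sites. On chromosomes 6, 11, 12 and 18 the first peak of the chromosome was a strong peak, at 3448277, 3099815, 3235263 and 3008586. On the other chromosomes it was not. Between 8 and 13 tags the number of peaks fell by a steady factor of 0.474 per added tag. Continued upwards, that decline gives 106 peaks of 14 or more tags, and the list held 3.71 times as many. It gives 1.21 peaks of 20 or more tags, and the list held 173. The tags per peak were recovered from the order of the list, and both the recovery and the limit of 14 tags were chosen after the list had been seen. With 1 library, no test between samples was possible.

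**Figure D1:**
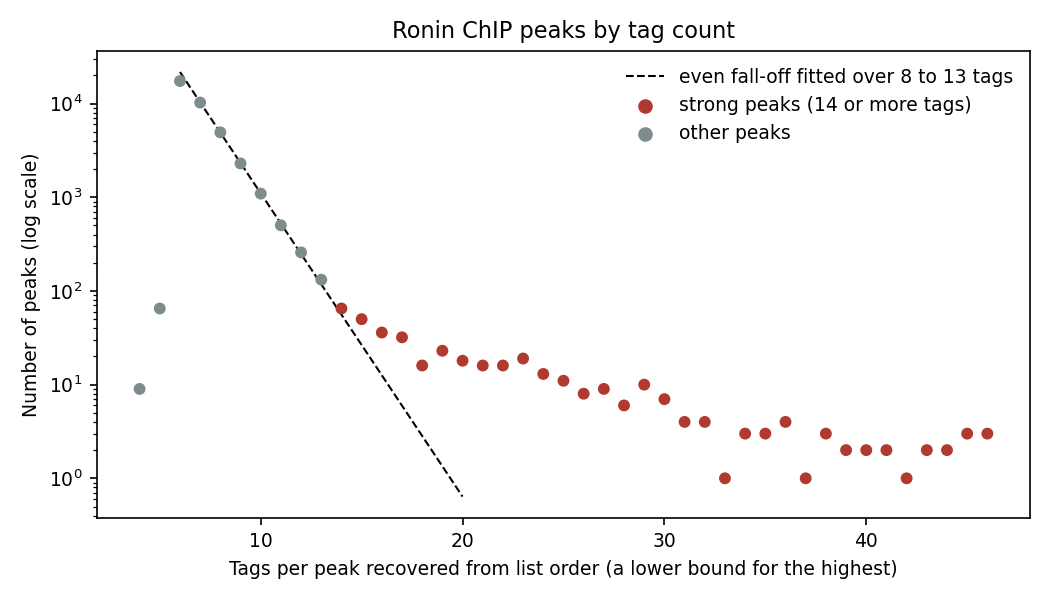
Number of Ronin ChIP peaks (log scale) at each tag count recovered from the order of the list. Grey points are peaks of under 14 tags, red points are strong peaks, and the dashed line is the even decline fitted over 8 to 13 tags, which meets the points there and falls below them from 14 tags upwards.

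The highest peaks were spread over several chromosomes. The 10 peaks ranked first in the list had at least 43 to 46 tags each, and 4 of them lay on chromosome 2. The first 2 lay close together on chromosome 2, at 98505179 to 98505369 and at 98506561 to 98506751, 1382 bp apart, with at least 46 tags each. The next was on the X chromosome at 139917497 to 139917687, also with at least 46 tags. Peaks of at least 45 tags followed on chromosome 2 at 77784365 to 77784555, on chromosome 9 at 24346439 to 24346629 and on chromosome 18 at 40467700 to 40467890. The other 4 lay on chromosome 2 at 181652523 to 181652713, chromosome 14 at 65568659 to 65568849, chromosome 8 at 124473920 to 124474110 and chromosome 15 at 102552548 to 102552738. The tag counts at this end of the list are lower bounds. Listing these 10 was decided after the data were seen. They are the highest peaks that the filters left: 41% of the candidates numbered 1 to 5 on each chromosome were missing from the list. The first 2 were numbered 3 and 4 on chromosome 2. Whether the control was also high at these 10 places was not examined, so they are not shown to be Ronin sites.

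The comparison of chromosomes asks whether peaks were spread in proportion to length. The X chromosome held far fewer peaks than its length gives: 1316 against 2361 expected, a ratio of 0.557. The autosomes lay much closer to their length. The lowest autosomes were chromosome 7, with 1958 peaks against 2168 (ratio 0.903), and chromosome 17, with 1239 against 1342 (ratio 0.923). The highest were chromosomes 18 (ratio 1.10), 3 (ratio 1.10) and 10 (ratio 1.10). A two-sided permutation test drew the peaks independently in proportion to length in 100000 resamples. With Benjamini-Hochberg adjustment over 20 chromosomes, 11 departed from length, 8 above it and 3 below it. The 3 below were chromosomes 7, 17 and X, with adjusted permutation p = 1e-04 for chromosomes 7 and X and 0.00893 for chromosome 17. The low X count raises the ratio of every autosome. Without the X chromosome, 9 autosomes departed, 4 above and 5 below. The ratio was then 1.07 for each of chromosomes 18, 3 and 10, 0.877 for chromosome 7 and 0.897 for chromosome 17. Length was taken as the span from the first to the last peak, 2568 Mb in all, and peaks within 1 library are not replicates.

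The X chromosome held fewer peaks than the autosomes in each tag class, and its ratio was lower in the higher classes, a trend that was not tested. Per Mb, the X chromosome held 0.541 times as many peaks as the autosomes (exact 95% interval 0.512 to 0.572). The ratio was 0.595 (0.550 to 0.643) for peaks of 6 tags, 0.508 (0.455 to 0.566) for 7 tags, 0.50 (0.438 to 0.570) for 8 or 9 tags and 0.422 (0.317 to 0.552) for 10 to 13 tags. For strong peaks it was 0.267 (0.107 to 0.556), from 7 peaks on the X chromosome and 388 on the autosomes. Per protein-coding gene the ratio was 0.781 (0.739 to 0.825) over all peaks, 0.858 (0.794 to 0.927) for 6 tags, 0.609 (0.457 to 0.796) for 10 to 13 tags and 0.386 (0.154 to 0.803) for strong peaks. These ratios were chosen after the chromosome counts were seen. They describe the peaks that the filters left. Read from gaps in the peak numbers, 13.4% of candidates were missing on the X chromosome, against 21% on the autosomes. This unequal removal raised the X ratio over all peaks, and its effect on each tag class is not known.

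Strong peaks were spread over the chromosomes in another way than the rest of the list. Chromosome 7 held 52 strong peaks against 22.9 expected from its length (ratio 2.27), although it held fewer peaks than its length gives when all heights were counted. The X chromosome held 7 against 25 expected (ratio 0.280). Chromosome 11, with 29 strong peaks against 18.3 expected, and chromosome 14, with 7 against 17.9, did not pass the adjusted test (adjusted permutation p = 0.0653 for each). The permutation test gave adjusted p = 0.0002 for chromosome 7 and adjusted p = 0.0045 for the X chromosome. The call on both was lost when strong peaks within 1 Mb of each other counted once, which merges more peaks where they are dense and left 17 loci on chromosome 7 (ratio 1.07, adjusted permutation p = 1.0) and 7 on the X chromosome (ratio 0.406, adjusted permutation p = 0.251). It was also lost against gene number in place of length, where 0 chromosomes departed, 3 had an unadjusted p under 0.05, and the adjusted permutation p was 0.126 for chromosomes 7 (52 against 37.1 expected) and X (7 against 17.6).

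Across the 20 chromosomes, strong peaks per Mb rose with protein-coding genes per Mb, and lower peaks did not show such a relation. Pearson's r was 0.78 (permutation p = 5e-05, adjusted p = 0.0003) and Spearman's rho was 0.78 (permutation p = 6e-05, adjusted p = 0.00036) for strong peaks. For peaks of 10 to 13 tags rho was 0.10 (permutation p = 0.666), and for peaks of 6 tags it was -0.26 (permutation p = 0.275). The family held 6 relations, adjusted by Benjamini-Hochberg. Without chromosomes 7 and 11, the 2 farthest from the median gene density, r for strong peaks was 0.60 (permutation p = 0.00835). The 10 chromosomes with most genes per Mb, which hold 49.6% of the span, carried 258 of the 395 strong peaks, or 65.3% (exact 95% interval 60.4% to 70.0%). They carried 51.7% (49.4% to 53.9%) of peaks of 10 to 13 tags and 49.5% (48.8% to 50.3%) of peaks of 6 tags. The odds ratio of strong peaks against peaks of 10 to 13 tags was 1.76 (95% interval 1.40 to 2.22, Fisher's exact test, two-sided p = 6.08e-07). Genes per chromosome were counted in assembly GRCm38, peaks are not independent of each other, and the relation was looked for after the data were seen.

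**Figure D2:**
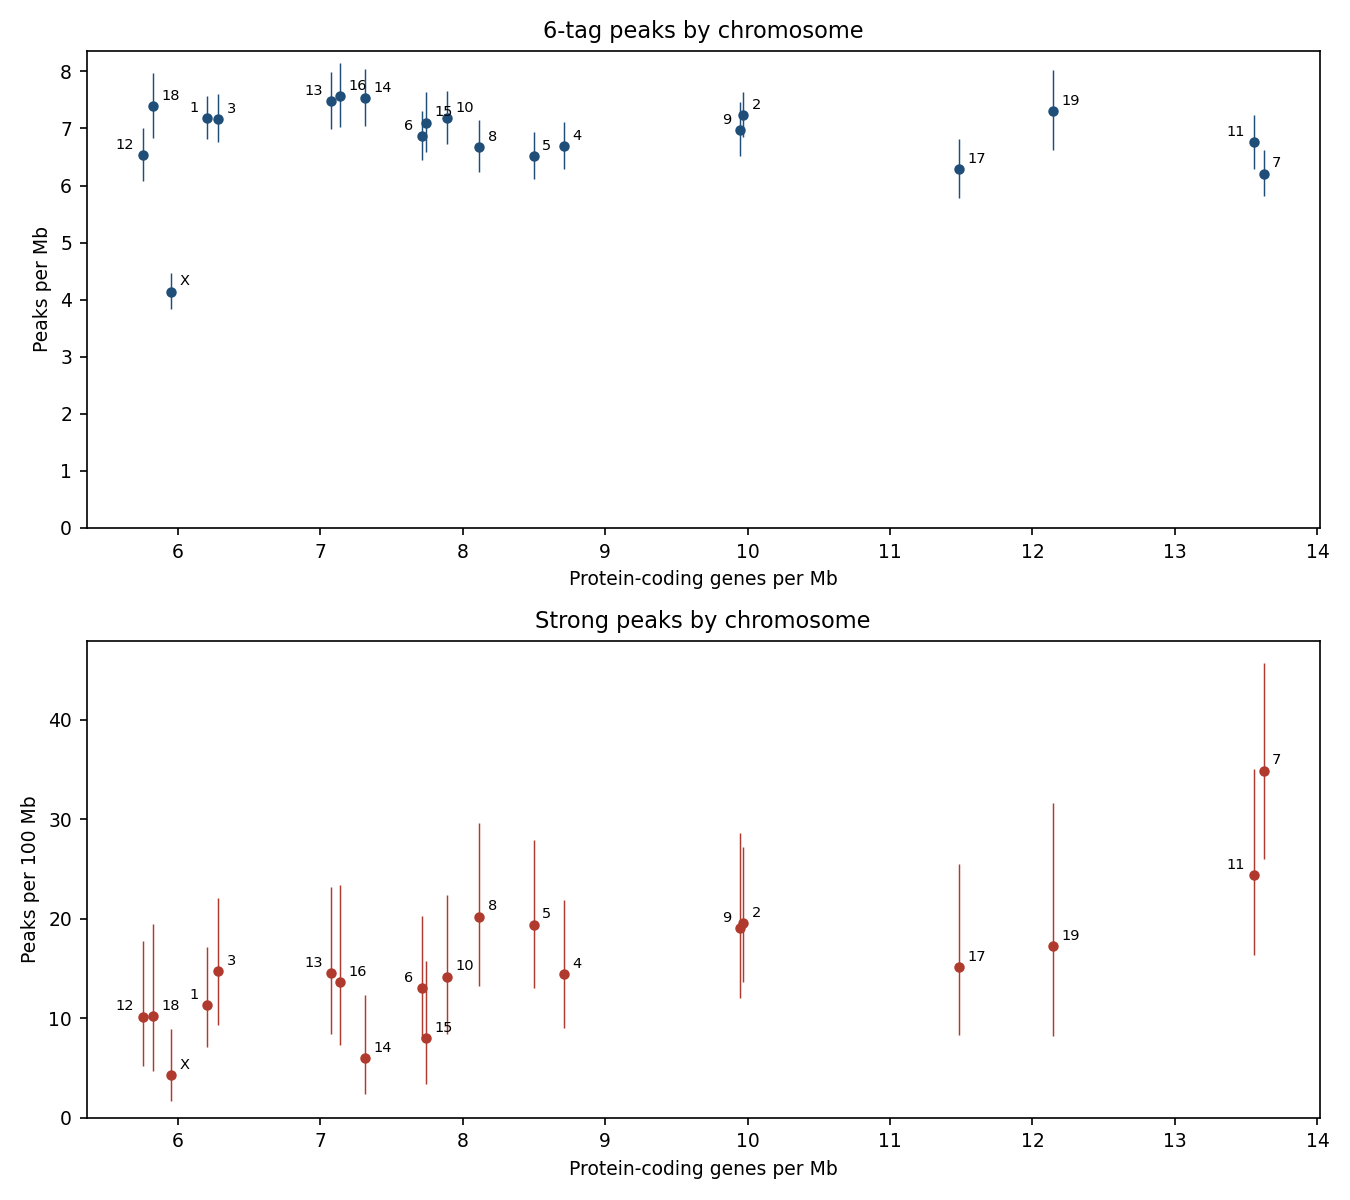
Peaks per Mb for 6-tag peaks and peaks per 100 Mb for strong peaks, against protein-coding genes per Mb, with 1 labelled point per chromosome. Bars are exact 95% Poisson intervals, and strong peaks reach 34.9 per 100 Mb on chromosome 7 while 6-tag peaks show no rise with gene density.

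The comparison of spacing asks whether peaks lie closer together than at random. Over the whole list, 13.7% of peaks had another peak within 5000 bp, and random placement within each chromosome gave 13.7% (ratio 1.00, one-sided permutation p = 0.480, 1000 placements). Strong peaks were close to each other far more often than at random. Within 5000 bp, 12 of 395 strong peaks (3.04%) had another strong peak, against 0.177% at random. Within 1 Mb, 47.3% of strong peaks had another, against 29.2% at random (ratio 1.62). Both differences had a one-sided permutation p = 0.001, the smallest the placements can give. Some strong neighbours lay very close, such as the peaks ranked 1 and 2 in the list, 1382 bp apart on chromosome 2. Another such pair began at 26023006 and 26023487 on chromosome 7. Whether such neighbours are separate sites or 1 enriched stretch called as several peaks was not tested. The share within 5000 bp therefore does not show that separate Ronin sites cluster. The peak caller was set to keep peaks 382 bp apart, with 1 closer pair in the list, and random placement that kept this distance gave a ratio of 1.07 for the whole list, with the same smallest p.

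The densest groups of strong peaks lay on chromosomes 3, 7, 8 and 13. Chromosome 3 at 88335652 to 89070557, chromosome 7 at 51629256 to 52318115 and chromosome 8 at 108232117 to 108939233 held 6 strong peaks each within 1 Mb. Chromosome 7 at 24866742 to 25055436 and chromosome 13 at 67209503 to 67825325 held 5 each. Against the highest window of the genome in 1000 random placements, permutation p = 0.004 for windows of 6 and permutation p = 0.019 for windows of 5. A further 3 windows with 4 strong peaks, 2 on chromosome 7 and 1 on chromosome 11, did not pass (permutation p = 0.342). The windows were chosen after the data were seen. As for spacing, placement was uniform along each chromosome's span and took no account of genes, mappable sequence or other peaks. In the order given, the 5 windows held 21, 14, 22, 18 and 20 peaks of any height within 1 Mb of their first strong peak, strong ones included. The list held 14.6 peaks per Mb.

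**Figure D3:**
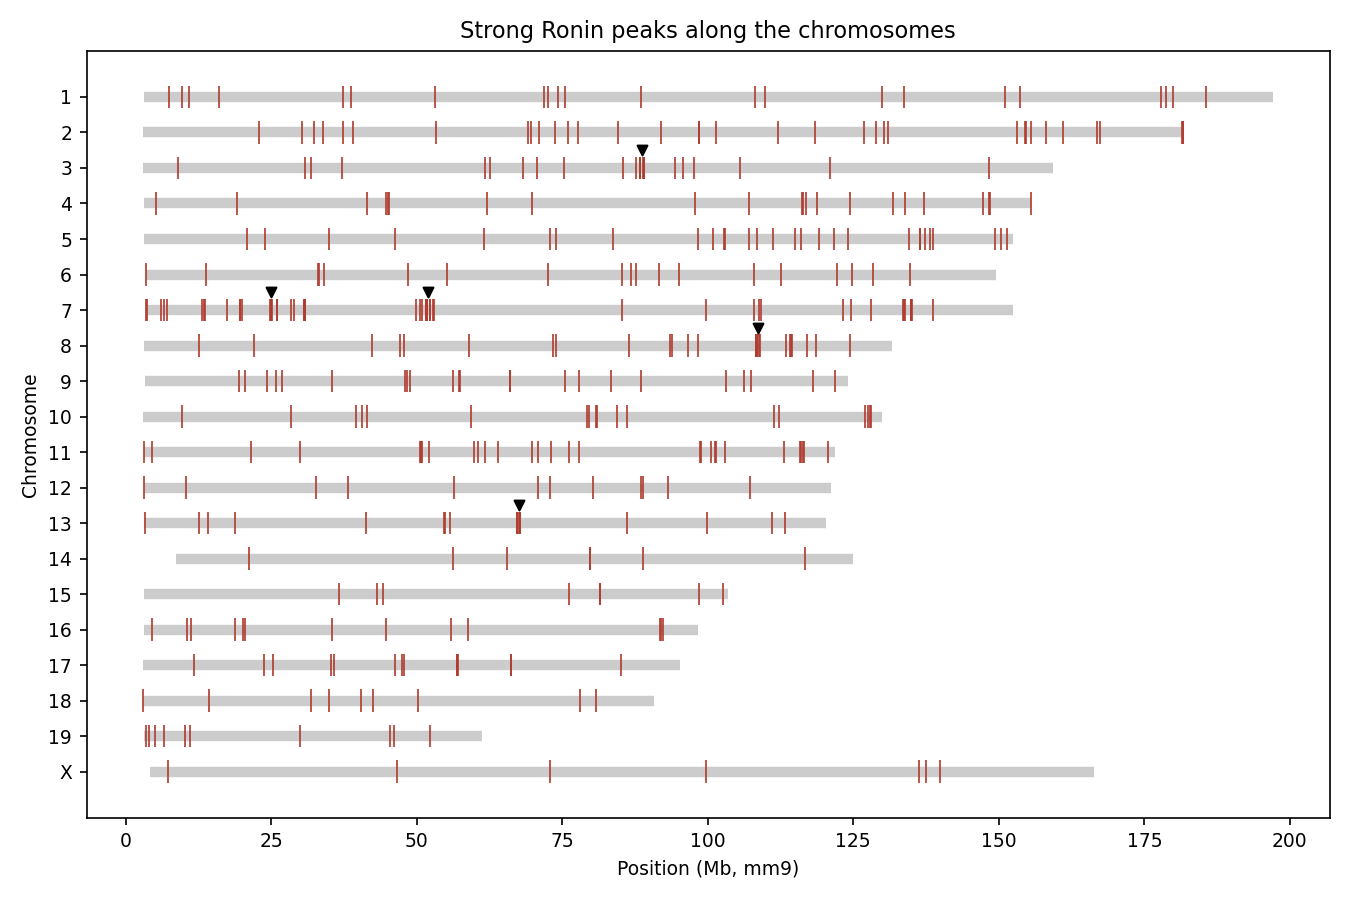
Position of each of the 395 strong peaks (red ticks, Mb in mm9) along the span of peaks on each chromosome (grey bars). Black triangles mark the 5 windows of 5 or 6 strong peaks on chromosomes 3, 7, 8 and 13.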

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

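All tests in this part were chosen after the numbering of the peaks had been seen. Peak numbers run within each chromosome roughly by falling tag count, and gaps in them were read as candidates that the filters removed: the numbers reach 47131 in all, against 47133 candidates in the header. This is a signal outside the peak comparisons. Of the candidates numbered 1 to 5 on each chromosome, 41 of 100 (41%, exact 95% interval 31.3% to 51.3%) were missing, against 20.7% of the rest (Fisher's exact test, two-sided p = 4.99e-06). The share missing was 26% for numbers 6 to 10, 21.4% for 11 to 50, 11.8% for 51 to 200 and 21.3% above 200. On the X chromosome 13.4% of candidates were missing, against 21% on the autosomes (Fisher's exact test, two-sided p = 5.21e-14).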

How the results depend on the processing

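Of the alternatives here, gene number for all peaks, other distances, merging within 500 bp and the highest-tag shares were planned, on a score that proved constant, so recovered tags stood in for it; the others were chosen after seeing the data. Keeping peaks of 7 or more tags left 19867 peaks, and 9 or more left 4677. Chromosomes departing from length fell from 11 to 3 in the latter and rose to 19 against gene number. For spacing, the ratio to random turned below 1 at 1000 bp (0.727) and for 6-tag peaks (0.945). It passed the test at 50000 bp (1.02), for 9 or more tags (1.70), with the minimum distance kept (1.07) and for strong peaks (17.1). The low value at 1000 bp falls where the minimum distance acts. Spearman's correlation of strong peaks with gene density was 0.41 at 10 or more tags (permutation p = 0.0753) and 0.66 to 0.79 in the other 9 alternatives. Chromosomes departing in strong peaks went from 2 to 0 against gene number, and to 0 when strong peaks within 1 Mb counted once, but stayed at 2 when those within 50 kb did. Counting within 1 Mb took chromosomes with displaced strong peaks from 4 to 0 on fewer loci, with Kolmogorov-Smirnov distances of 0.366 before and 0.324 after on chromosome 5, 0.493 and 0.357 on 7, 0.362 and 0.243 on 8, and 0.520 and 0.494 on 19. Distances from fewer loci run higher by chance, so these do not settle whether the displacement stayed. The X ratio moved from 0.541 to 0.595, 0.508, 0.50, 0.422 and 0.267 with rising tags, and to 0.781 per gene. Where no reason is given, the cause was not tested. Alternatives on promoters, motifs, gene lists and scores at promoters were not run. At this depth the X ratio of strong peaks rests on 7 peaks.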

Other observations

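Every test in this part was chosen after the data were first examined, and for 2 of them, counting clustered strong peaks once and the 6- to 9-tag peaks near strong ones, the bound was set before that result was seen.

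Within chromosomes, strong peaks lay elsewhere than 6-tag peaks on 4 of 20 chromosomes in an exact Kolmogorov-Smirnov test adjusted by Benjamini-Hochberg: 5, 7, 8 and 19. On chromosome 7 the median strong peak lay at 50.3 Mb and the median 6-tag peak at 91.8 Mb (adjusted exact p = 2.96e-10). On chromosome 19 the medians were 10.6 and 30.5 Mb (adjusted exact p = 0.0279). With strong peaks within 1 Mb counted once, none of the 20 passed the adjusted test and 3 had an unadjusted p under 0.05. On chromosome 7 the median was then 49.9 Mb over 17 loci in place of 52 peaks. Its Kolmogorov-Smirnov distance went from 0.493 to 0.357 (unadjusted exact p = 0.0207, adjusted exact p = 0.207). On chromosome 19 the distance went from 0.520 to 0.494.

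Strong peaks followed gene-dense chromosomes. Uneven depth would place 10- to 13-tag peaks there as often, and the odds ratio between the classes was 1.76 among peaks that the filters left. The filters acted unevenly: 26.9% of candidates were missing on chromosome 11, against 21% on all autosomes. The odds ratio argues against uneven depth only if the filters took both classes alike, which was not tested. A few clusters as the whole cause is argued against by a rho of 0.66 after strong peaks within 1 Mb counted once. The excess on chromosome 7 itself was lost, however. On those 273 loci the chi-square against length over all chromosomes did not pass either (permutation p = 0.215). Signal that any immunoprecipitation gives at active genes cannot be told apart from Ronin binding, since the control was not analysed here. The removal of 41% of the first 5 candidates per chromosome does not decide this. Gaps in the numbers do not say which filter removed a candidate or whether it lay at a gene. Ronin binding near genes may be the source, but no biological explanation was tested.

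Peaks of 6 to 13 tags made up most of the list. A uniform Poisson background would give a ratio of 7-tag to 6-tag peaks of 0.0471, and 0.589 was seen. Weak binding gathered around strong sites is argued against for 6 to 9 tags, whose number within 50 kb of a strong peak was 0.982 times random, while for 10 to 13 tags it was 1.65 times random (two-sided permutation p = 0.002). Within 5000 bp the ratios were 0.642 (two-sided permutation p = 0.01) and 2.33 (two-sided permutation p = 0.0599), at distances where the caller's filter on local signal acts. A background that varies from place to place and scattered weak binding cannot be told apart: 6-tag peaks had a 6-tag neighbour 0.945 times as often as at random within 5000 bp, where the filters lower this ratio, and 1.04 times within 50000 bp.

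The X chromosome held fewer peaks of every class. Its gene number does not account for this in 6-tag peaks, which did not rise with gene density and were at 0.595 of the autosomal density, while for strong peaks the ratio per gene of 0.386 (0.154 to 0.803) came with an adjusted permutation p of 0.126 and leaves gene number open. An even loss of X reads was compared with nested counts that also held the strong peaks. Autosomal tags were thinned at random to a share of 0.816, set by the X density at 6 or more tags. That gave 267 peaks of 8 or more tags against 298 seen (exact 95% Poisson interval 265 to 334). At 10 or more tags the X held 0.961 times the number it gave. These peaks are also part of the fitted count. An excess in some tag classes and a lack in others can cancel in such counts. The thinning therefore does not settle whether an even loss lowers the counts below 14 tags. It also used the peaks left by the filters, which removed a smaller share of candidates on the X chromosome than on the autosomes. The share was fitted and not set against the loss that copy number would give, so it says nothing for or against copy number. For strong peaks the same share gave 16.7 against 7 seen, 0.418 times as many and outside the interval of 2.81 to 14.4, which argues against an even loss as the whole cause there. The sex of the pups is not given in the sources used here, and neither uneven mapping nor a difference in Ronin binding on the X chromosome was tested.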
